A study of Rattus norvegicus with 71 samples.

How the data were processed

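Total RNA was taken from whole lung of Lewis, Fisher and Brown Norway rats at postnatal days 1, 7 and 14 after in utero exposure to saline or ovalbumin, made into biotinylated cRNA and hybridized to rat bead arrays with 22523 probes, on 6 slides of 11 or 12 arrays. All 71 arrays were assigned to 18 groups of strain, age and exposure (4 arrays each, 3 in Fisher PN7 saline) from titles and characteristics, which give the exposure in words. The short labels mark saline with a plus sign and ovalbumin with a minus sign. No litter, sex or animal is given. A further characteristic, a choice of samples for an analysis of reproducibility, was not used.

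The authors deposited, per the file headers, raw mean bead signal intensities without background correction or normalization, and a detection p-value for every probe and array against the negative control beads of the array. Their deposited log2 values equal the log2 raw signal after quantile normalization over all arrays without background correction, to within 5.0e-05. The labels name lumi without a version.

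Raw signals were background corrected, quantile normalized and log2 transformed with neqc of limma 3.58.1, using the detection p-values and an offset of 16, in R 4.3.3 with the data.table package (version 1.17.8). Figures and further tables used Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Probes with a detection p-value under 0.01 on at least 3 arrays were tested, 14019 in all. The probe annotation gives 13793 probes exactly 1 symbol, 0 probes several, and the others none. Of the probes tested, 9848 have a symbol (9642 genes, 197 of them with several probes) and 4171 do not. Where a gene had several probes the one with the highest mean was used.

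One linear model with a mean for each of the 18 groups (53 residual degrees of freedom) was fitted with limma, with moderated statistics and a trend. The comparisons were the age steps in saline arrays averaged over strains, their difference between strains, the strain differences in saline arrays averaged over ages, ovalbumin against saline in each strain at each age and averaged over strains, and the F tests of whether the exposure effect differed between strains or between ages. Adjusted p-values are Benjamini-Hochberg values over the probes tested, called under 0.05. Where 1 group was undetected on every array, the fold is a lower bound, with the lowest detected signal of each array in its place, and is given as "at least".

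Genes were named by a fixed rule, among probes with exactly 1 symbol that is not a systematic name and an adjusted p under 0.05. For the age steps these were the 10 largest rises and 10 largest falls with the same direction in all 3 strains. For strains they were the 8 highest and 8 lowest with the same direction at all 3 ages. For each exposure comparison and mean they were the 5 largest rises and 5 largest falls, and for each F test the 5 lowest p-values. Up to 4 members of lowest p were added from each called gene list, and Cftr, Sftpc, Eln and Scgb1a1 in every age comparison. Some members added from lists are left out of the text.

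The 29 gene lists for cell types and processes were fixed at the same time, and 28 had at least 4 measured genes. They were tested with camera of limma at its preset correlation between genes of 0.01, and again with the correlation estimated for each list, with Benjamini-Hochberg adjustment over the lists of a comparison. Members were also tested with adjustment over the list alone.

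The developmental index of an array is its least squares position between the PN1 and PN14 saline means over probes called between these ages in the other two strains. It was compared between exposures by exact permutation of the arrays. The fit was also tested on simulated data in which 100 probes changed 1.5-fold and 100 changed 2-fold.

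Samples, comparisons, tests, the naming rule and the alternatives were chosen before the data were examined. The alternatives were the authors' values, no background correction, no detection filter, slide as a fixed term or a random block, fits of only the groups compared, fits within 1 slide, replicate letter as a block, and leaving out each array. The letters were taken to pair arrays only in Fisher PN7, where the deviations of all 3 pairs from their group means correlated over 0.1 (0.351, 0.433 and 0.340 for a, b and c). The labels do not say what a letter marks, and replicates a and b of both exposures lay on slide 4. Leaving out 4 arrays in doubt (Lewis PN1 ovalbumin a, Fisher PN1 saline a, Lewis PN7 saline d and Fisher PN7 saline c) was added after the data were seen, as were a block by pair in Fisher PN7 and a list of liver genes.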

Results

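Gene expression was measured in whole lung of newborn rats on bead arrays, where labelled cRNA bound to probes is read by fluorescence. The 71 arrays cover 3 inbred strains (Lewis, Fisher and Brown Norway), 3 postnatal ages (days 1, 7 and 14, written PN1, PN7 and PN14) and 2 exposures in utero, saline or the egg protein ovalbumin, a model allergen. The 18 groups held 4 arrays each (Fisher PN7 saline 3). No litter or animal is given, so every p-value measures the spread between these samples. Limma pools it over groups, where it ran from 0.158 to 0.336 (root mean square deviation). Per array 10128 to 12437 probes were detected (median 11217), the median raw signal ran from 118 to 182. Changes are log2 differences with standard errors from 1 limma fit, and a probe was called at an adjusted p under 0.05. For each gene list, members called up and down over all 14019 probes tested come first, then those adjusted over the list alone, then the camera test with its preset correlation.

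The first comparison asked how unexposed lung changed between PN1 and PN7, averaged over the strains (12 and 11 saline arrays). Alox15, a lipoxygenase of macrophages and eosinophils, rose by 3.66 ± 0.31, and the macrophage elastase Mmp12 rose by 1.78 ± 0.19. Dlk1, an imprinted growth regulator, fell by 3.22 ± 0.35, and the embryonic globin Hbe1 fell by 2.06 ± 0.38. Of the measured genes, 16 of 19 of the cell cycle and 4 of 8 of MHC class II rose, and 8 of 9 glucocorticoid-responsive genes fell. The fit called 6585 probes, 3402 higher and 3183 lower at PN7.

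Other large rises were Ccl19, a chemokine of lymphoid tissue (2.04 ± 0.33), the secreted proteins Nell1 (2.07 ± 0.28), Angptl2 (1.89 ± 0.18) and Spon2 (1.78 ± 0.18), the calcium-binding protein S100a4 (1.72 ± 0.12), the lectin Lgals5 (2.08 ± 0.27), the membrane skeleton protein Add2 (1.68 ± 0.24) and Ucp1, the uncoupling protein of brown fat (2.70 ± 0.84). The largest falls included the neutrophil defensins RatNP-3b (-2.54 ± 0.34) and Np4 (-2.13 ± 0.32), the protease inhibitor Stfa3 (-2.11 ± 0.53), the enzyme Adhfe1 (-2.53 ± 0.21), osteopontin (Spp1, -2.16 ± 0.23), the protocadherin Pcdh20 (-2.11 ± 0.28), the endothelial proteoglycan Esm1 (-2.06 ± 0.25) and the muscle protein Trim54 (-1.97 ± 0.35). Sftpc, a surfactant protein of alveolar type 2 cells (0.04 ± 0.07, adjusted p = 0.717), the club cell secretoglobin Scgb1a1 (0.02 ± 0.04, adjusted p = 0.806) and elastin (Eln, 0.27 ± 0.12, adjusted p = 0.0601) did not pass. Eln passed, at 0.30 to 0.34, without Lewis PN1 saline c, Fisher PN1 saline d, Lewis PN7 saline d, Fisher PN7 saline c or Brown Norway PN7 saline c. No probe is paired with the chloride channel gene Cftr.

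The cell cycle list had 16 up and 1 down of 19 (16 and 1 over the list alone), adjusted p = 0.000309, or 0.413 with an estimated correlation. Cdc20 (1.25 ± 0.17) and Ube2c (1.15 ± 0.14) rose, with 2.01 and 1.94 in Lewis but 0.04 and -0.35 in Fisher, and Aurkb fell (-1.02 ± 0.09). The glucocorticoid-responsive list had 0 up and 8 down of 9 (0 and 8 over the list alone), adjusted p = 0.000412, or 0.378 with an estimated correlation. Fkbp5, a co-chaperone of the glucocorticoid receptor, had -1.29 ± 0.23 and the transcription factor Klf9 had -1.15 ± 0.18. Matrix and elastic fibre genes had 11 up and 1 down of 18 (14 and 1 over the list alone), adjusted p = 0.00174, or 0.378 with an estimated correlation. The collagen gene Col3a1 rose (0.69 ± 0.10) and the crosslinking enzyme Lox fell (-0.77 ± 0.10). MHC class II genes, which present antigen, had 4 up and 0 down of 8 (4 and 0 over the list alone), adjusted p = 0.0198, or 0.378 with an estimated correlation. RT1-Db1 had 1.41 ± 0.15. Interferon-induced genes had 7 up and 1 down of 14 (7 and 1 over the list alone), adjusted p = 0.0187, or 0.378 with an estimated correlation. The immunoproteasome subunit Psmb9 had 1.10 ± 0.16. The neutrophil list had 0 up and 7 down of 9 (1 and 7 over the list alone), adjusted p = 0.0187, or 0.388 with an estimated correlation. The calprotectin subunit S100a8 had -0.98 ± 0.13. Sterol synthesis genes had 1 up and 6 down of 8 (1 and 6 over the list alone), adjusted p = 0.0198, or 0.378 with an estimated correlation. Sqle had -0.90 ± 0.11 and Idi1 had -1.01 ± 0.14. The endothelial list had 5 up and 1 down of 9 (6 and 1 over the list alone), adjusted p = 0.0301, or 0.378 with an estimated correlation. Von Willebrand factor (Vwf) had 1.00 ± 0.11 and the receptor Tek had -0.41 ± 0.08. B cell genes had 4 up and 0 down of 4 (4 and 0 over the list alone), adjusted p = 0.0351, or 0.378 with an estimated correlation. The antigen receptor subunit Cd79b had 0.73 ± 0.13. The B cell list lost its call without Brown Norway PN7 saline a. PN1 and PN7 saline arrays shared no slide, and with slide as a fixed term the count was 3662 and 9 of the 35 named genes past the test lost their call (S100a8, RatNP-3b, Ccl19, Np4, Stfa3, Tek, Ucp1, Fkbp5 and Trim54).

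Between PN7 and PN14 (11 and 12 saline arrays) 14 of 19 cell cycle genes fell, and 8 of 10 alveolar type 1 genes and all 4 B cell genes rose. The tight junction gene Cldn11 rose by 2.18 ± 0.14, the eosinophil chemokine Ccl11 by 1.73 ± 0.14 and the polymeric immunoglobulin receptor Pigr by 1.64 ± 0.15. The defensins RatNP-3b and Defa5 fell by 2.63 ± 0.34 and 2.48 ± 0.31. Elastin rose by 0.70 ± 0.12 (adjusted p = 4.31e-06), while Sftpc (-0.11 ± 0.07, adjusted p = 0.222) and Scgb1a1 (-0.05 ± 0.04, adjusted p = 0.338) did not pass, but Sftpc passed without Brown Norway PN7 saline b (-0.18). The fit called 6314 probes, 3083 higher and 3231 lower at PN14.

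Thrsp, a regulator of lipid synthesis, rose by 2.96 ± 0.44, Ucp1 by 2.86 ± 0.84, Fam180a by 1.89 ± 0.16, the membrane protein Slitrk6 by 1.81 ± 0.15, Nell1 by 1.73 ± 0.28, the schlafen Slfn4 by 1.62 ± 0.21 and the lymphocyte activation marker Cd69 by 1.60 ± 0.27. Falls were seen for the retinoic acid binding protein Crabp1 (-2.22 ± 0.22), the alcohol dehydrogenase Adh1c (-1.69 ± 0.11), the muscle genes Acta1 (-1.93 ± 0.72) and Myh3 (-1.67 ± 0.61), and the liver genes Alb (-2.03 ± 0.66), Ahsg (-1.75 ± 0.59) and Afp (-1.85 ± 0.57, at least 1.66-fold lower, PN14 being below background). Liver genes, a list added after the data were seen, were high in Lewis PN7 saline replicate d, and Ahsg lost its call without it (-1.23, adjusted p = 0.0543).

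In the cell cycle list there were 0 up and 14 down of 19 (0 and 16 over the list alone), adjusted p = 2.11e-06, or 0.384 with an estimated correlation. Ube2c had -1.18 ± 0.14 and the replication licensing factor Mcm5 had -1.16 ± 0.13. Alveolar type 1 genes had 8 up and 0 down of 10 (9 and 0 over the list alone), adjusted p = 0.00271, or 0.208 with an estimated correlation. The caveolin Cav2 had 1.16 ± 0.17 and the homeodomain protein Hopx had 0.58 ± 0.08. Imprinted and growth genes had 0 up and 7 down of 7 (0 and 7 over the list alone), adjusted p = 0.00327, or 0.0816 with an estimated correlation. Dlk1 had -1.90 ± 0.35, insulin-like growth factor 2 (Igf2) -0.82 ± 0.16 and the cell cycle inhibitor Cdkn1c -0.83 ± 0.10. Matrix genes had 9 up and 0 down of 18 (9 and 0 over the list alone), adjusted p = 0.00508, or 0.384 with an estimated correlation. Col3a1 had 0.67 ± 0.10 and periostin (Postn) had 0.58 ± 0.09. Erythroid genes had 0 up and 8 down of 12 (0 and 8 over the list alone), adjusted p = 0.00508, or 0.384 with an estimated correlation. The haemoglobin chaperone Ahsp had -1.23 ± 0.20, and the transcription factor Gata1 was at least 1.26-fold lower (-1.14 ± 0.19). B cell genes had 4 up and 0 down of 4 (4 and 0 over the list alone), adjusted p = 0.00508, or 0.208 with an estimated correlation. Ms4a1 (CD20) had 1.26 ± 0.21 and Cd79b had 0.96 ± 0.13. PN7 and PN14 saline arrays shared no slide, and with slide as a fixed term the count was 3502 and Crabp1, Afp, Ahsg, Eln, Acta1, Myh3, Ube2c, Ucp1, Alb and Mcm5 lost their call (Acta1 and Myh3 also in 7 and 5 fits that left out 1 array). Both age steps use the same PN7 arrays.

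Whether the age profile of unexposed lung differed between strains was asked with an F test, which called 5190 probes. Fcer1a, the chain of the mast cell IgE receptor that binds IgE, was at least 2.32-fold higher at PN14 than at PN1 in Brown Norway and below background on all other saline arrays (adjusted p = 1.50e-16 for the difference). Pon3, a lactonase, gave from PN1 to PN14 2.34 in Brown Norway, 0.30 in Lewis and 0.16 in Fisher (adjusted p = 4.30e-12). In Lewis the odorant-binding and urinary protein genes Obp3 and Mup4l3 were at least 3.45-fold and 5.97-fold lower at PN14 and Mup4l4 gave -3.39, all 3 being above background on at most 1 Fisher array of these ages (adjusted p = 4.90e-13, 5.43e-12 and 1.12e-11).

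The strain comparisons asked which genes differed between unexposed lungs over all ages (12 Lewis, 11 Fisher and 12 Brown Norway arrays), and the 3 comparisons share arms. Against Lewis, the MHC class I genes RT1-CE16 and RT1-A2 were at least 48.4-fold and 17.2-fold higher in Brown Norway, and Plekhf2 at least 31.1-fold, the Lewis arrays being below background. Echdc2, a mitochondrial enzyme, was at least 20.1-fold lower. The fit called 3275 probes, 1628 higher and 1647 lower. Probe sequences were not compared with each strain's genome, so a probe that binds the transcript of 1 strain less well would give such values too.

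Also higher were Ankra2 (4.28 ± 0.15), the ribosomal genes Rpl30 (4.13 ± 0.10) and Mrpl18 (3.99 ± 0.09), the peroxisomal gene Pxmp4 (3.88 ± 0.13) and Ly6i (3.17 ± 0.13). Lower were the receptor Qrfpr (-4.06 ± 0.20), the interferon-inducible GTPase Ifi47 (at least 6.22-fold), the urinary protein Mup5 (-2.62 ± 0.24), the globin Hbb-b1 (-2.60 ± 0.23), the leukocyte gene Lst1 (at least 3.59-fold), the phosphatase Plpp1 (-2.51 ± 0.12) and Plekhh1 (-2.44 ± 0.14). The endothelial list had 6 up and 0 down of 9 (7 and 0 over the list alone), adjusted p = 0.000764, or 0.0396 with an estimated correlation. Vwf had 0.98 ± 0.11 and the claudin Cldn5 had 0.46 ± 0.05. Smooth muscle and myofibroblast genes had 1 up and 6 down of 10 (1 and 7 over the list alone), adjusted p = 0.00360, or 0.0396 with an estimated correlation. Synpo2 had -0.97 ± 0.11 and the actin Actg2 had -0.67 ± 0.12. Mast cell and eosinophil genes had 6 up and 2 down of 12 (9 and 2 over the list alone), adjusted p = 0.00360, or 0.171 with an estimated correlation. The mast cell protease Mcpt1 (1.33 ± 0.14) was higher, as was Fcer1a (above background on 4 of 12 Brown Norway and 0 Lewis arrays), and the stem cell factor receptor Kit (-0.77 ± 0.15) was lower. B cell genes had 2 up and 0 down of 4 (2 and 0 over the list alone), adjusted p = 0.00360, or 0.160 with an estimated correlation. The adaptor Blnk had 1.96 ± 0.13 (at least 2.68-fold). Interferon-induced genes had 5 up and 0 down of 14 (5 and 0 over the list alone), adjusted p = 0.0359, or 0.582 with an estimated correlation. The peptide transporter Tap1 had 0.80 ± 0.11. Ciliated cell genes had 0 up and 7 down of 12 (0 and 8 over the list alone), adjusted p = 0.00360, or 0.378 with an estimated correlation. The dynein light chain Dynlrb2 had -0.57 ± 0.08. The interferon list lost its call in 3 fits that left out 1 array.

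Against Lewis, Fisher lung had less Hba-a3, an alpha globin gene (-6.98 ± 0.31), less lipocalin 2 (Lcn2, -3.92 ± 0.27), an iron-sequestering defence protein, and at least 12.6-fold less of the polyamine enzyme Odc1. Plekhf2 was at least 24.0-fold higher, and the class I genes RT1-CE16 and RT1-S2 at least 6.67-fold and 3.08-fold. The fit called 2193 probes, 1118 higher and 1075 lower in Fisher. Mrpl18 (4.03 ± 0.09), Rpl30 (4.00 ± 0.10), RT1-A3 (2.63 ± 0.11), kallikrein B1 (Klkb1, 2.43 ± 0.14) and Commd6 (2.27 ± 0.17) were higher, and Washc3 (-5.35 ± 0.10), Qrfpr (-3.63 ± 0.21), Sorbs2 (at least 7.25-fold), Plekhh1 (-3.28 ± 0.15) and the transporter Slco1a5 (-3.08 ± 0.16) were lower. Cell cycle genes had 8 up and 0 down of 19 (9 and 0 over the list alone), adjusted p = 0.00355, or 0.937 with an estimated correlation. Ube2c (0.66 ± 0.14) and the kinase Plk1 (0.69 ± 0.20) were higher, with 2.17 and 2.03 at PN1 against -0.08 and -0.03 at PN14. Interferon-induced genes had 5 up and 0 down of 14 (9 and 0 over the list alone), adjusted p = 0.00507, or 0.902 with an estimated correlation. Mx2 had 1.27 ± 0.21 and Oas1a had 0.48 ± 0.17, and Oas1a lost its call in most fits that left out 1 array.

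Against Fisher, Brown Norway lung had more Hba-a3 (7.11 ± 0.31), Lcn2 (4.04 ± 0.27) and Mcpt10, a mast cell protease (1.80 ± 0.16). The fit called 4519 probes, 2211 higher and 2308 lower in Brown Norway. Also higher were Washc3 (5.25 ± 0.10), Odc1 (at least 12.7-fold), RT1-A2 and Ankra2 (each at least 17.0-fold), Ly6i (3.91 ± 0.13) and Pxmp4 (3.77 ± 0.14). Lower were Echdc2, Ifi47, the lipid phosphatase Mtmr1, Lst1 and Plcxd3 (at least 20.4-fold, 7.66-fold, 2.98-fold, 3.13-fold and 2.31-fold), Klkb1 (-2.49 ± 0.14), Commd6 (-2.38 ± 0.17) and Nell2 (-2.10 ± 0.10). The cell cycle list had 0 up and 16 down of 19 (0 and 17 over the list alone), adjusted p = 1.08e-05, or 0.399 with an estimated correlation. Ube2c had -0.96 ± 0.14 and Mcm2 had -0.67 ± 0.12. B cell genes had 3 up and 0 down of 4 (3 and 0 over the list alone), adjusted p = 0.00242, or 0.128 with an estimated correlation. Cd79b had 1.15 ± 0.13. Smooth muscle genes had 1 up and 7 down of 10 (1 and 7 over the list alone), adjusted p = 0.00564, or 0.0727 with an estimated correlation. Synpo2 had -1.21 ± 0.12 and Actg2 had -0.85 ± 0.13. Ciliated cell genes had 0 up and 6 down of 12 (1 and 7 over the list alone), adjusted p = 0.0114, or 0.398 with an estimated correlation. Dynlrb2 had -0.66 ± 0.09. Matrix genes had 1 up and 11 down of 18 (1 and 13 over the list alone), adjusted p = 0.0158, or 0.399 with an estimated correlation. The fibulin Fbln1 was lower (-0.72 ± 0.11) and Col3a1 higher (0.81 ± 0.10). Mast cell genes had 6 up and 2 down of 12 (6 and 2 over the list alone), adjusted p = 0.0321, or 0.398 with an estimated correlation. Kit was again lower (-0.80 ± 0.15). Heart and skeletal muscle genes had 0 up and 4 down of 11 (0 and 6 over the list alone), adjusted p = 0.0496, or 0.594 with an estimated correlation. Creatine kinase (Ckm) had -1.37 ± 0.49 and the atrial peptide Nppa had -1.54 ± 0.62. Both calls were lost in several fits that left out 1 array, as was the call of this list in 14 and of the mast cell list in 2.

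The exposure comparisons asked whether ovalbumin in utero changed the lung in each strain at each age, with 4 arrays per group (3 for Fisher PN7 saline). In Brown Norway pups at PN1, 7 of 9 glucocorticoid-responsive genes, 6 of 10 clock genes and 7 of 13 antioxidant and xenobiotic genes fell after ovalbumin. Cell cycle (8 of 19), matrix (9 of 18), MHC class II (5 of 8) and cytokine genes (7 of 13) rose. Fkbp5 (-2.13 ± 0.39) and Klf9 (-2.13 ± 0.31) fell, whereas Mmp12 and the chemokine Ccl12 rose at least 4.86-fold and 2.62-fold. The fit called 3684 probes, 1921 higher and 1763 lower, with 715 over 2-fold.

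Other rises were the carbonic anhydrase Car3 (2.55 ± 0.69), the amino acid transporter Slc7a10 (2.52 ± 0.30) and apelin (Apln, 2.29 ± 0.23). The largest falls were Trim54 (-4.32 ± 0.59), cystathionine beta-synthase (Cbs, -4.12 ± 0.46), Pcdh20 (at least 6.34-fold), the neuropeptide galanin (Gal, -3.42 ± 0.33) and Mlc1 (-3.18 ± 0.43). Glucocorticoid-responsive genes had 1 up and 7 down of 9 (1 and 7 over the list alone), adjusted p = 0.00108, or 0.277 with an estimated correlation. The leucine zipper protein Tsc22d3 fell (-1.34 ± 0.24), and the member that rose was the metallothionein Mt1 (1.56 ± 0.20). Antioxidant and xenobiotic genes had 1 up and 7 down of 13 (1 and 9 over the list alone), adjusted p = 0.00108, or 0.208 with an estimated correlation. The monooxygenase Fmo2 had -2.77 ± 0.40 and the quinone reductase Nqo1 had -1.34 ± 0.18. Clock genes had 0 up and 6 down of 10 (0 and 7 over the list alone), adjusted p = 0.00108, or 0.0739 with an estimated correlation. Bmal1 had -1.14 ± 0.18 and Tef had -1.30 ± 0.26. In the cell cycle list there were 8 up and 1 down of 19 (11 and 1 over the list alone), adjusted p = 0.00155, or 0.620 with an estimated correlation. The licensing factors Mcm3 (1.81 ± 0.37) and Mcm2 (1.30 ± 0.20) rose and Aurkb (-0.60 ± 0.15) fell. MHC class II genes had 5 up and 0 down of 8 (5 and 0 over the list alone), adjusted p = 0.00155, or 0.277 with an estimated correlation. RT1-Ba had 1.55 ± 0.24. Interferon-induced genes had 7 up and 0 down of 14 (9 and 0 over the list alone), adjusted p = 0.00435, or 0.348 with an estimated correlation. The GTPase Gbp2 had 1.43 ± 0.21. Matrix genes had 9 up and 1 down of 18 (9 and 1 over the list alone), adjusted p = 0.0114, or 0.426 with an estimated correlation. The elastic fibre proteins Mfap4 (1.49 ± 0.26) and Fbln5 (0.98 ± 0.18) rose and Lox (-0.73 ± 0.17) fell. Inflammatory genes had 7 up and 1 down of 13 (8 and 1 over the list alone), adjusted p = 0.0114, or 0.277 with an estimated correlation. The monocyte chemokine Ccl2 had 1.54 ± 0.26 and the adhesion molecule Icam1 had 0.92 ± 0.16. Developmental signalling genes had 4 up and 0 down of 13 (5 and 0 over the list alone), adjusted p = 0.00660, or 0.286 with an estimated correlation. Wnt5a had 1.60 ± 0.25 and Shh had 0.79 ± 0.19. The neutrophil list had 0 up and 4 down of 9 (0 and 5 over the list alone), adjusted p = 0.0342, or 0.477 with an estimated correlation. Lcn2 had -1.37 ± 0.46, a call lost without saline c (-1.33), saline d (-1.28) or ovalbumin a (-1.28). The interferon list lost its call without ovalbumin b (adjusted p = 0.0690) and the neutrophil list without ovalbumin c (0.0699). Within slide 3 the count was 700.

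In Lewis pups at PN7 all 19 cell cycle genes fell after ovalbumin, such as the ribonucleotide reductase subunit Rrm2 (-3.30 ± 0.36), Ube2c (-2.98 ± 0.24) and Mcm2 (-1.92 ± 0.20). The elastic fibre gene Mfap4 fell by 2.86 ± 0.26, whereas Klf9 rose by 1.71 ± 0.31 and the clock gene Per1 by 2.22 ± 0.40. The fit called 4938 probes, 2562 higher and 2376 lower, with 1161 over 2-fold.

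The largest rises were Cbs (4.16 ± 0.46), Adhfe1 (3.92 ± 0.35), Esm1 (3.68 ± 0.43), the apolipoprotein Apoc1 (3.67 ± 0.61) and the transcription factor Klf15 (3.06 ± 0.38). The largest falls were the replication-linked Pclaf (-4.39 ± 0.48), Car3 (-4.26 ± 0.69), the mitotic kinase Pbk (-4.18 ± 0.48, at least 13.2-fold), Crabp1 (-3.95 ± 0.38) and the kinetochore gene Kntc1 (-3.61 ± 0.40, at least 9.14-fold). Cell cycle genes had 0 up and 19 down of 19 (0 and 19 over the list alone), adjusted p = 1.13e-18, or 0.144 with an estimated correlation. Matrix genes had 2 up and 11 down of 18 (2 and 13 over the list alone), adjusted p = 2.90e-05, or 0.165 with an estimated correlation. Fbln5 had -1.79 ± 0.18 and the collagen gene Col1a2 had -0.96 ± 0.11. Smooth muscle genes had 2 up and 5 down of 10 (2 and 6 over the list alone), adjusted p = 0.0473, or 0.165 with an estimated correlation. Actg2 had -1.98 ± 0.21 and transgelin (Tagln) had -1.35 ± 0.19. Glucocorticoid-responsive genes had 6 up and 0 down of 9 (7 and 0 over the list alone), adjusted p = 0.0123, or 0.406 with an estimated correlation. Fkbp5 had 1.58 ± 0.39 and Tsc22d3 had 1.46 ± 0.24. Clock genes had 5 up and 0 down of 10 (5 and 0 over the list alone), adjusted p = 0.00808, or 0.144 with an estimated correlation. Bmal1 had 1.18 ± 0.18. Antioxidant and xenobiotic genes had 8 up and 1 down of 13 (9 and 1 over the list alone), adjusted p = 0.00277, or 0.165 with an estimated correlation. Fmo2 had 2.44 ± 0.40 and Nqo1 had 1.17 ± 0.18. Alveolar type 2 and surfactant genes had 6 up and 0 down of 10 (6 and 0 over the list alone), adjusted p = 0.0307, or 0.406 with an estimated correlation. The phosphate transporter Slc34a2 had 0.83 ± 0.17 and surfactant protein B (Sftpb) had 0.72 ± 0.15. Ciliated cell genes had 5 up and 0 down of 12 (5 and 0 over the list alone), adjusted p = 0.0239, or 0.406 with an estimated correlation. Lrrc23 had 0.76 ± 0.13. MHC class II genes had 0 up and 5 down of 8 (0 and 5 over the list alone), adjusted p = 0.0239, or 0.406 with an estimated correlation. The invariant chain Cd74 had -1.07 ± 0.23 and RT1-Db1 had -1.24 ± 0.25. The smooth muscle (6 of 8 fits), alveolar type 2 (4), MHC class II (3) and ciliated lists (2) lost their call without 1 array, with adjusted p up to 0.0874. The count was 2880 within slide 2 and 1926 within slide 4.

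**Figure D1:**
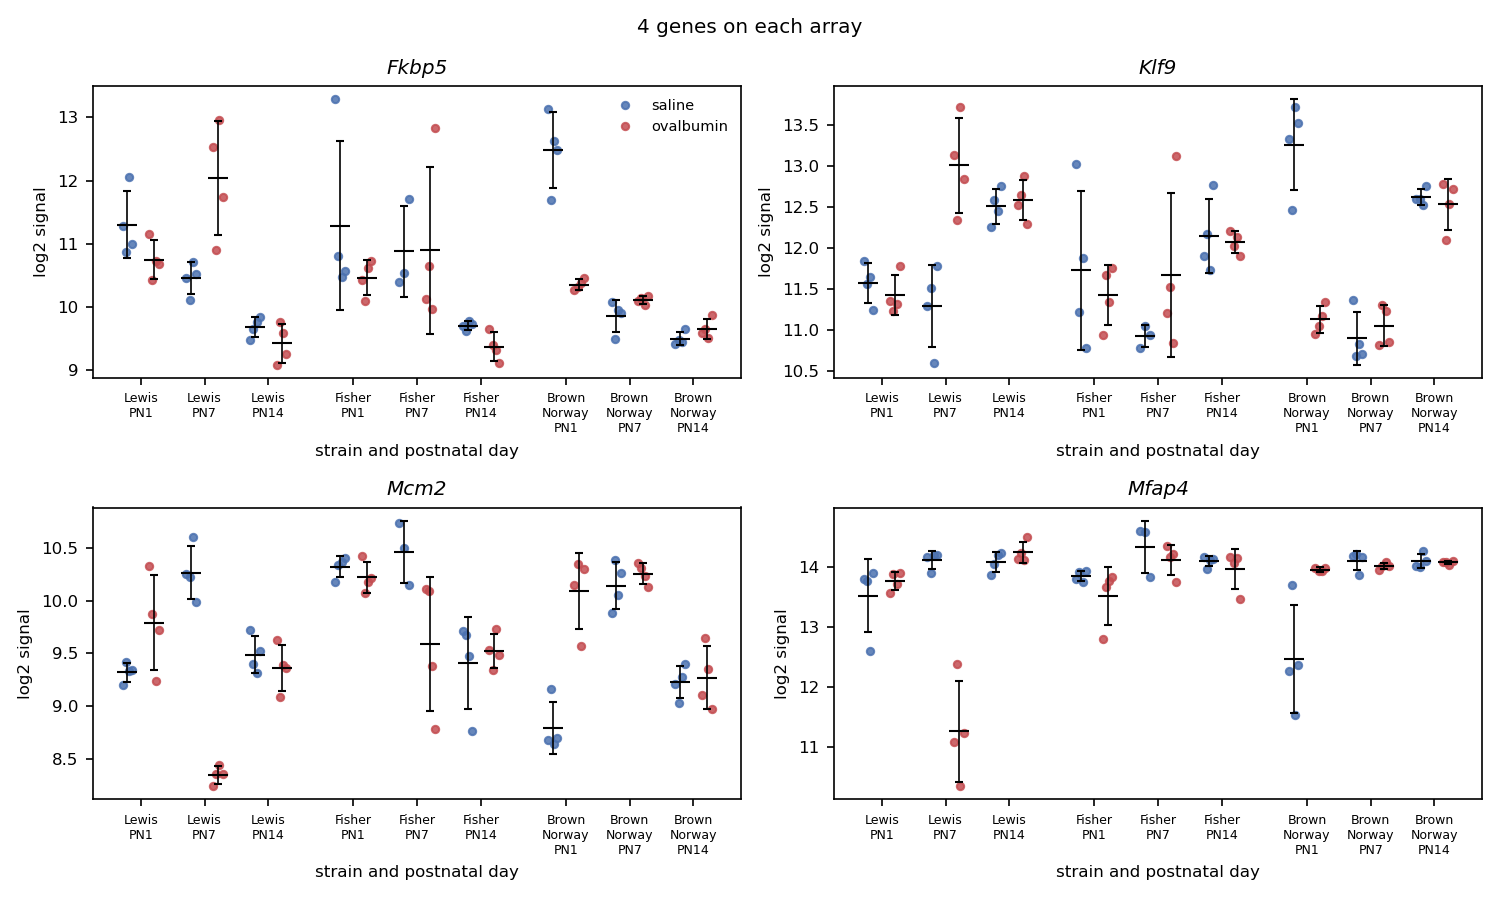
Log2 signal (vertical axes) of Fkbp5, Klf9, Mcm2 and Mfap4 on each array, by strain and postnatal day (horizontal axes), with points for single arrays and bars for the mean and SD of each exposure. Ovalbumin means lay below saline for Fkbp5 and Klf9 in Brown Norway PN1 and above in Lewis PN7 (4 arrays per group), with the reverse for Mcm2 and Mfap4.

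These 2 comparisons share no array. Of the 3684 and 4938 probes called, 2159 were called in both, against 1298 if the lists were independent, and 95.3% of the 2159 went in opposite directions. Across probes, which are not independent replicates, the changes correlated with Pearson's r = -0.595 and Spearman's rho = -0.529.

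In Lewis pups at PN1 the T cell receptor chain Cd3g rose by 3.05 ± 0.54 after ovalbumin, the chain Cd3d at least 4.61-fold and the co-receptor Cd8a by 2.53 ± 0.55. In ovalbumin replicate a the mean of 9 T cell genes lay 4.99 above the other arrays of the group. Without it Cd3g had 1.54 (adjusted p = 0.00315), while Cd3d (adjusted p = 0.452), Cd8a (1.04, adjusted p = 0.312) and Ptprcap (0.74, adjusted p = 0.434) did not pass. The fit called 24 probes, 16 higher and 8 lower. Ptprcap, a leukocyte phosphatase partner, rose by 2.03 ± 0.47 and the connexin Gjb2 by 1.96 ± 0.44. Anks1a (-1.15 ± 0.22), the joint lubricant Prg4 (-1.13 ± 0.27), the scaffold Nherf2 (-0.82 ± 0.18), the endothelial transcription factor Sox17 (-0.70 ± 0.14) and the lectin Clec4b2 (at least 1.10-fold) fell. T cell genes had 3 up and 0 down of 9 (8 and 0 over the list alone), adjusted p = 1.23e-11, or 0.163 with an estimated correlation. The cell cycle (0 up and 0 down of 19, 10 and 0 over the list alone), thymocyte (0 and 0 of 4, 3 and 0), MHC class II (0 and 0 of 8, 2 and 0) and macrophage (0 and 0 of 8, 3 and 0) lists gave adjusted p = 3.40e-08, 0.00970, 0.00970 and 0.00970, or 0.309, 0.256, 0.309 and 0.233 with an estimated correlation, all upward. The interferon-induced (0 up and 0 down of 14, 3 and 0 over the list alone), type 2 and asthma-related (0 and 0 of 7, 0 and 0), mast cell and eosinophil (0 and 0 of 12, 3 and 0) and alveolar type 1 (0 and 0 of 10, 0 and 3) lists gave adjusted p = 0.00970, 0.0115, 0.0147 and 0.00970, or 0.335, 0.163, 0.309 and 0.256 with an estimated correlation, the last downward and the others upward. Without ovalbumin a only the T cell (adjusted p = 0.00436) and cell cycle lists kept their call, and the thymocyte list had adjusted p = 0.775. The count was 13 (6 higher and 7 lower) with the authors' deposited values, and 0 when only the groups compared were fitted (limma, 1793 probes at an unadjusted p under 0.05) or within slide 3 (853). Leaving out 1 array gave 39 (saline a), 51 (saline b), 6 (saline c), 6 (saline d), 7 (ovalbumin a), 131 (ovalbumin c) or 54 (ovalbumin d), and each of the 10 named genes lost its call in some alternative.

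In Fisher pups at PN1 the cyclin Ccnb2 fell by 2.05 ± 0.32 after ovalbumin, Ube2c by 2.03 ± 0.24 and the mitotic activator Cdc20 by 1.89 ± 0.29. Nkx2-1, a transcription factor of lung epithelium, rose by 1.55 ± 0.37. The fit called 386 probes, 204 higher and 182 lower. The carboxypeptidase Cpa4 (2.36 ± 0.41) and the urinary protein genes Mup5 (2.19 ± 0.41), Mup4 (at least 2.81-fold) and Mup4l4 (at least 2.79-fold) also rose, and the spindle genes Knstrn (-2.26 ± 0.36), Kif11 (-2.05 ± 0.42) and Kif20a (-2.01 ± 0.34) fell. The cell cycle list had 0 up and 12 down of 19 (0 and 14 over the list alone), adjusted p = 4.20e-23, or 0.0574 with an estimated correlation. Alveolar type 2 genes had 4 up and 0 down of 10 (4 and 0 over the list alone), adjusted p = 2.97e-06, or 0.0574 with an estimated correlation. Slc34a2 had 0.73 ± 0.17 and Sftpb had 0.51 ± 0.15. Alveolar type 1 genes had 2 up and 0 down of 10 (2 and 0 over the list alone), adjusted p = 0.0161, or 0.296 with an estimated correlation. The receptor Ager had 0.64 ± 0.16 and the water channel Aqp5 had 0.91 ± 0.25. Ciliated cell genes had 3 up and 0 down of 12 (8 and 0 over the list alone), adjusted p = 2.97e-06, or 0.0574 with an estimated correlation. Spag6l had 0.67 ± 0.15 and Tppp3 had 0.57 ± 0.15. Sterol synthesis genes had 2 up and 0 down of 8 (7 and 1 over the list alone), adjusted p = 2.13e-05, or 0.0574 with an estimated correlation. Sqle had 0.85 ± 0.19 and Fdft1 had 0.84 ± 0.18. The glucocorticoid-responsive list had 0 up and 1 down of 9 (0 and 1 over the list alone), adjusted p = 0.0248, or 0.510 with an estimated correlation. The member past the test was Mt1 (-0.78 ± 0.20). This list lost its call in 2 fits (adjusted p = 0.820 without saline a), as did the alveolar type 1 list (0.117 without ovalbumin a). Liver genes lay 5.08 above the other arrays in saline replicate a. The count was 710 with slide as a fixed term, 236 when only the groups compared were fitted, 255 without saline replicate b, and 169 without ovalbumin replicate b. Nkx2-1, Slc34a2, Sftpb, Ager, Aqp5, Spag6l, Tppp3 and Mt1 each lost their call in at least 1 fit that left out an array.

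In Fisher pups at PN7 the replication genes Mcm2 (-0.87 ± 0.21), Mcm10 (-1.18 ± 0.32) and Cdc6 (-1.26 ± 0.36) and the kinase Aurkb (-0.78 ± 0.16) fell after ovalbumin. S100a8 (1.08 ± 0.25), the neutrophil collagenase Mmp8 (1.03 ± 0.28) and the cytokine Il1b (1.03 ± 0.25) rose. The fit called 281 probes, 150 higher and 131 lower. Also higher were the muscle genes Apobec2 (1.77 ± 0.46) and Asb11 (1.50 ± 0.33), the water channel Aqp8 (at least 1.49-fold), the GTPase Rhoa (1.54 ± 0.40), the erythroid gene Hemgn (1.49 ± 0.39) and the glutathione synthesis gene Gclm (0.72 ± 0.17). Lower were the lectin Reg3b (-1.48 ± 0.40), Cdca7 (-1.20 ± 0.34) and Nrgn (-1.10 ± 0.31). In the cell cycle list there were 0 up and 3 down of 19 (0 and 9 over the list alone), adjusted p = 9.65e-10, or 0.363 with an estimated correlation. The neutrophil and granulocyte (3 up and 0 down of 9, 4 and 0 over the list alone), antioxidant and xenobiotic metabolism (2 and 0 of 13, 4 and 0) and inflammatory cytokine and chemokine (1 and 0 of 13, 3 and 0) lists gave adjusted p = 0.00101, 0.0182 and 0.0371, or 0.363, 0.363 and 0.363 with an estimated correlation, all upward. The glucocorticoid-responsive (0 up and 0 down of 9, 2 and 0 over the list alone), erythroid (1 and 0 of 12, 3 and 0), heart and skeletal muscle (0 and 0 of 11, 0 and 0) and immediate early (0 and 0 of 11, 1 and 0) lists gave adjusted p = 0.00347, 0.0411, 0.0371 and 0.0454, or 0.363, 0.630, 0.630 and 0.630 with an estimated correlation, also upward. Each but the cell cycle list lost its call in 1 to 4 of 7 fits that left out 1 array. The count was 6 with slide as a fixed term, and 0 when only the groups compared were fitted (limma, 1356 probes at an unadjusted p under 0.05) or within slide 4 (587). With a replicate block by pair in Fisher PN7, added after the result was seen and to which ovalbumin d adds nothing, the count was 22 (14 higher and 8 lower). Of the genes named here only Reg3b (-1.78, adjusted p = 0.0109) and of the 8 lists only the cell cycle (camera adjusted p = 1.99e-04) and inflammatory lists (0.0114) kept their call. Reg3b had -0.30 (adjusted p = 0.747) without saline a, and without ovalbumin d Nrgn had -0.67, Cdc6 -0.62 and Cdca7 -0.53, none of them called, nor was Aqp8 (adjusted p = 0.198). Leaving out 1 array gave 144 (saline a), 133 (saline c), 541 (ovalbumin a), 152 (ovalbumin c) or 8 (ovalbumin d).

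In Brown Norway pups at PN7 the myeloid chemokine receptor Ccr1 (0.83 ± 0.15), the IgG receptor Fcgr1a (0.74 ± 0.17), the DNA repair gene Nbn (0.81 ± 0.17), Tmem135 (0.77 ± 0.17) and the ammonia transporter Rhcg (0.73 ± 0.17) rose after ovalbumin. Cdkn1c (-0.78 ± 0.17), the growth factor inhibitor Spry1 (-0.70 ± 0.16), Dpf2 (-0.83 ± 0.19), Ccdc32 (-0.66 ± 0.15) and Gpkow (-0.59 ± 0.13) fell. The fit called 21 probes, 12 higher and 9 lower. The B cell and plasma cell (0 up and 0 down of 4, 2 and 0 over the list alone), developmental signalling (0 and 0 of 13, 0 and 1) and endothelial (0 and 0 of 9, 0 and 1) lists gave adjusted p = 0.0496, 0.0368 and 0.0368, or 0.663, 0.663 and 0.663 with an estimated correlation, the first upward and the others downward, each losing its call in 5 of 8 fits that left out 1 array. No slide held both groups. The count was 793 with slide as a fixed term and 0 with slide as a random block (limma, 2008 probes at an unadjusted p under 0.05) or when only the groups compared were fitted (1018). Leaving out 1 array gave 599 (saline a), 287 (saline c), 2 (ovalbumin c), 1 (ovalbumin d) or, by limma, 0 (saline b, saline d, ovalbumin a and ovalbumin b, with 1066, 1997, 1711 and 1835 probes at an unadjusted p under 0.05), and each of the 10 named genes lost its call in some alternative, Tmem135 (0.47) and Dpf2 (-0.53) without saline b.

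In Brown Norway pups at PN14 the transcription factor Egr2 rose by 0.77 ± 0.14, the only call against 380 probes at an unadjusted p under 0.05, and it lost its call (0.68 to 0.76) in 6 of 8 fits that left out 1 array and with slide as a random block (limma, 0 probes, 225 at an unadjusted p under 0.05). Other immediate early genes, which respond quickly to stimulation, did not pass: Fos had 1.98 ± 0.52 (adjusted p = 0.624), Egr1 1.76 ± 0.44 (adjusted p = 0.442) and Ccn1 1.34 ± 0.32 (adjusted p = 0.334). Immediate early genes had 1 up and 0 down of 11 (7 and 0 over the list alone), adjusted p = 2.08e-21, or 0.000354 with an estimated correlation. Inflammatory genes had 0 up and 0 down of 13 (1 and 0 over the list alone), adjusted p = 0.000868, or 0.0990 with an estimated correlation.
In Fisher 2 probes fell (588 at an unadjusted p under 0.05), the neuronal receptor Sorcs3 (at least 1.14-fold, not called without saline d or ovalbumin b) and ILMN_1366588, which has no gene name and was singled out after its values were seen (-0.97 ± 0.19, adjusted p = 0.0255). The neutrophil and granulocyte (0 up and 0 down of 9, 0 and 3 over the list alone), sterol and fatty acid synthesis (0 and 0 of 8, 1 and 0), T cell (0 and 0 of 9, 0 and 0) and alveolar type 2 and surfactant (0 and 0 of 10, 0 and 0) lists gave adjusted p = 3.56e-05, 0.000799, 0.00559 and 0.0111, or 0.302, 0.302, 0.906 and 0.576 with an estimated correlation, the first downward and the others upward. T cell genes lay 1.21 above the other arrays in ovalbumin replicate a, and that list lost its call without it (adjusted p = 0.427), as did the last without ovalbumin d (0.234).
In Lewis limma called 0 probes, with 348 at an unadjusted p under 0.05. Cell cycle genes had 0 up and 0 down of 19 (0 and 0 over the list alone), adjusted p = 0.000536, or 0.472 with an estimated correlation. In data simulated for Lewis PN14 the fit recovered 44% of 100 probes changed 1.5-fold and 90% of 100 changed 2-fold, with 8 false calls. Exposure and slide cannot be told apart at PN14: saline arrays lay on slides 1 and 5 and ovalbumin arrays on slide 6, except Fisher ovalbumin replicate d on slide 2, and the counts with slide as a fixed term (1486 in Lewis, 692 in Fisher and 694 in Brown Norway) rest on that array and hold no probe called without the term, so not Egr2. Fitting only the groups compared gave 52 for Brown Norway.

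**Figure D2:**
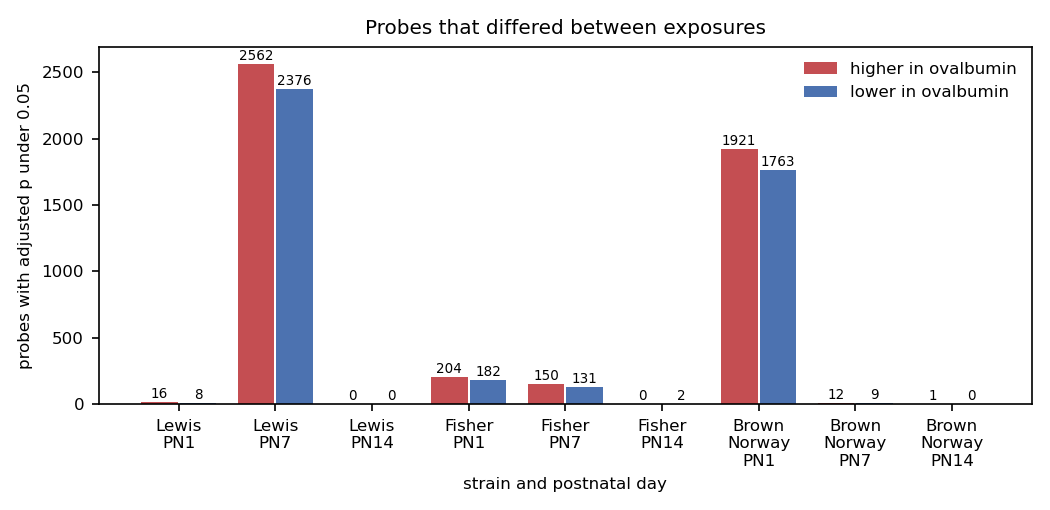
Probes that differed between ovalbumin and saline (vertical axis, number with adjusted p under 0.05) for each strain and postnatal day (horizontal axis), with bars for higher and lower probes. Brown Norway PN1 (3684) and Lewis PN7 (4938) hold most of the calls, and no PN14 group has more than 2.

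The mean of the strains at each age asked for shared effects (12 arrays per exposure, 11 for PN7 saline). At PN1 the interferon-induced Mx2 rose by 0.98 ± 0.21, with 0.54, 0.95 and 1.44 in Lewis, Fisher and Brown Norway, and Ccl19 by 1.01 ± 0.32 (1.20, 0.87 and 0.96). Fkbp5 fell by 1.17 ± 0.22, with -0.55, -0.82 and -2.13. The fit called 1529 probes, 843 higher and 686 lower. Other named genes had a larger difference in 1 strain: Mmp12 (1.27 ± 0.18, at least 4.86-fold in Brown Norway), Trim54 (-1.91 ± 0.34, -4.32), Cbs (-1.53 ± 0.26, -4.12), Pcdh20 (-1.45 ± 0.27, at least 6.34-fold), Gal (-1.33 ± 0.19, -3.42), RT1-Ba (0.76 ± 0.14, 1.55) and the transcription factor Zbtb16 (at least 1.06-fold), and Cd3g (1.08 ± 0.31, with 3.05 in Lewis) and Cd8a (1.03 ± 0.32, 2.53). Glucocorticoid-responsive genes had 1 up and 6 down of 9 (1 and 8 over the list alone), adjusted p = 1.17e-05, or 0.123 with an estimated correlation. MHC class II genes had 5 up and 0 down of 8 (6 and 0 over the list alone), adjusted p = 2.44e-05, or 0.123 with an estimated correlation. The interferon-induced (7 up and 0 down of 14, 9 and 0 over the list alone), T cell (2 and 0 of 9, 4 and 0), B cell and plasma cell (2 and 0 of 4, 4 and 0) and ciliated (3 and 0 of 12, 4 and 0) lists gave adjusted p = 1.56e-05, 0.00172, 0.00613 and 0.00266, or 0.123, 0.339, 0.137 and 0.266 with an estimated correlation, all upward. The sterol and fatty acid synthesis (2 up and 0 down of 8, 3 and 0 over the list alone), mast cell and eosinophil (2 and 0 of 12, 3 and 0), inflammatory cytokine and chemokine (4 and 1 of 13, 4 and 1) and circadian clock (0 and 3 of 10, 0 and 6) lists gave adjusted p = 0.0193, 0.0214, 0.0312 and 0.0144, or 0.304, 0.266, 0.266 and 0.137 with an estimated correlation, the last downward and the others upward. The T cell list had adjusted p = 0.0417 without Lewis PN1 ovalbumin a, and the sterol, mast cell and inflammatory lists lost their call without Fisher PN1 ovalbumin a (0.0768, 0.0818 and 0.0900). The count was 790 with slide as a fixed term and 35 within slide 3, and Ccl19 lost its call in 7 fits that left out 1 array. Without Lewis PN1 ovalbumin a Ccl19 had 0.60 (adjusted p = 0.105), Cd3g 0.58 (adjusted p = 0.00972) and Cd8a 0.53 (adjusted p = 0.0322), and without Brown Norway PN1 saline c Cd8a did not pass (0.97, adjusted p = 0.0531).

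At PN7 all 19 cell cycle genes fell in the mean over strains, such as Mcm3 (-1.45 ± 0.22, with -2.74, -1.06 and -0.54 in Lewis, Fisher and Brown Norway) and the cyclin Ccna2 (-1.48 ± 0.26, with -3.44, -0.99 and -0.03). Klf9 rose by 0.87 ± 0.18 (1.71, 0.75 and 0.15) and S100a8 by 0.72 ± 0.13 (0.64, 1.08 and 0.45). The fit called 3175 probes, 1523 higher and 1652 lower. Other named genes differed most in Lewis: Adhfe1 (1.59 ± 0.21, with 3.92 in Lewis), the antiviral gene Oas1k (1.47 ± 0.21, 2.76), Cbs (1.45 ± 0.27, 4.16), Esm1 (1.44 ± 0.25, 3.68) and RatNP-3b (1.40 ± 0.34, 2.85) rose, and the centromere gene Cenpt (-1.65 ± 0.23, -3.59), Pclaf (-1.62 ± 0.28, -4.39), Crabp1 (-1.59 ± 0.22, -3.95) and Mfap4 (-1.05 ± 0.15, -2.86) fell. The cell cycle list had 0 up and 19 down of 19 (0 and 19 over the list alone), adjusted p = 9.98e-19, or 0.158 with an estimated correlation. Matrix genes had 1 up and 9 down of 18 (1 and 11 over the list alone), adjusted p = 0.000391, or 0.280 with an estimated correlation. The antioxidant and xenobiotic metabolism (7 up and 0 down of 13, 10 and 0 over the list alone), glucocorticoid-responsive (5 and 0 of 9, 6 and 0), neutrophil and granulocyte (5 and 0 of 9, 5 and 0) and circadian clock (5 and 0 of 10, 5 and 0) lists gave adjusted p = 0.000391, 0.00123, 0.00373 and 0.0202, or 0.158, 0.280, 0.347 and 0.218 with an estimated correlation, all upward. The count was 1955 with slide as a fixed term and 1772 when only the groups compared were fitted.

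At PN14 the mean over strains called 2 probes, both lower and without a gene name (ILMN_1366588, -0.62 ± 0.11, adjusted p = 0.00625, and ILMN_1360353, -0.76 ± 0.15, adjusted p = 0.0413, singled out after their values were seen), against 1045 at an unadjusted p under 0.05. The immediate early (0 up and 0 down of 11, 2 and 0 over the list alone), T cell (0 and 0 of 9, 0 and 0), endothelial (0 and 0 of 9, 2 and 0), alveolar type 2 and surfactant (0 and 0 of 10, 0 and 0) and cell cycle (0 and 0 of 19, 0 and 0) lists gave adjusted p = 8.27e-06, 0.00238, 0.0364, 0.0476 and 0.0364, or 0.430, 0.742, 0.585, 0.742 and 0.803 with an estimated correlation, the last downward and the others upward. The T cell list had adjusted p = 0.0380 without Fisher PN14 ovalbumin a, high in T cell genes, and the last 3 lists lost their call in 9 to 14 of 24 fits that left out 1 array. Slide and exposure are confounded here too, the count being 1572 with slide as a fixed term, without these 2 probes, and 0 with slide as a random block (limma, 379 at an unadjusted p under 0.05).

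**Figure D3:**
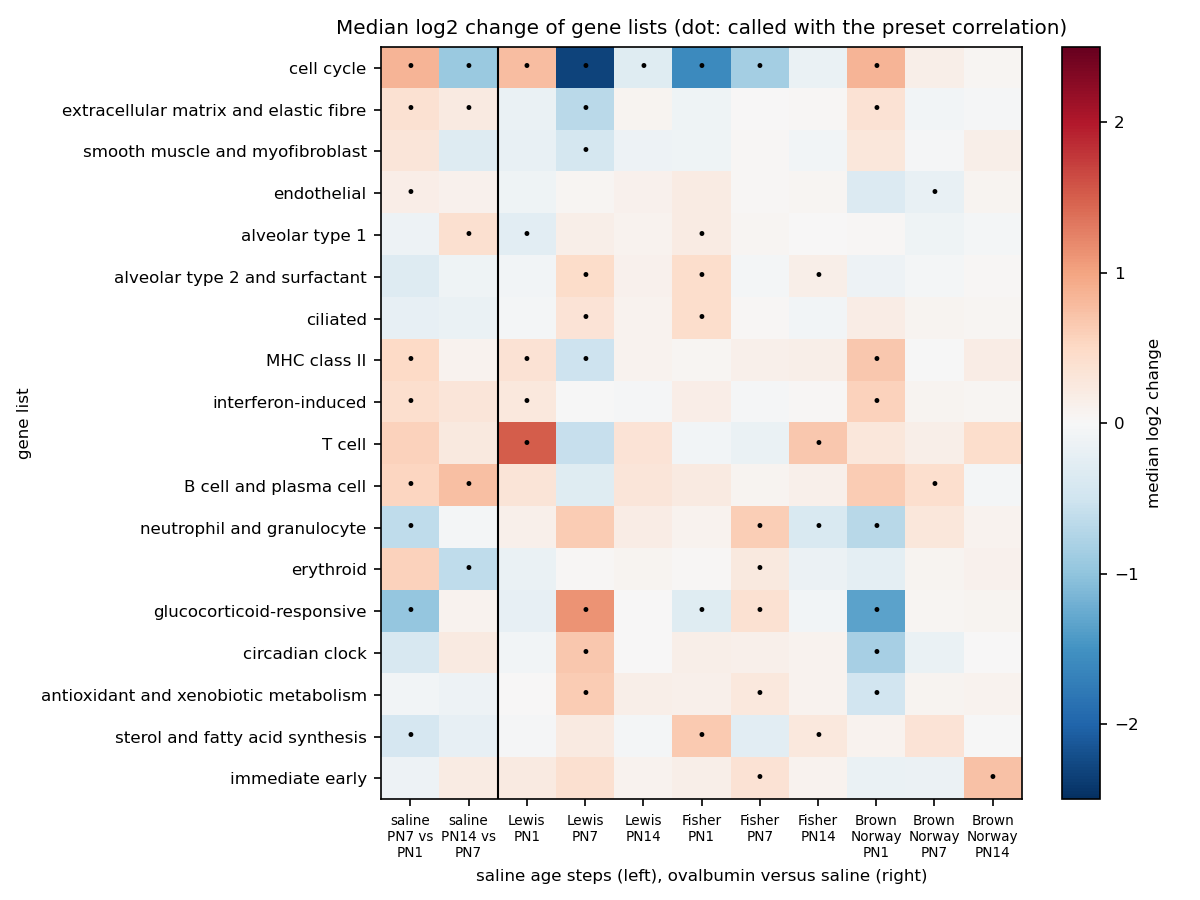
Median log2 change (colour) of 18 of the fixed gene lists (vertical axis) in the saline age steps (left) and in ovalbumin against saline for each strain and age (right), with a dot where the list was called with the preset correlation. Cell cycle genes had a median of 0.85 in Brown Norway PN1 and -2.32 in Lewis PN7.

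Whether the exposure effect differed between strains was tested directly at each age. At PN1 3175 probes were called. Prg4 gave -1.13 in Lewis, 1.24 in Fisher and -2.09 in Brown Norway (adjusted p = 1.25e-08), and Pon3 gave 0.22, -0.48 and 1.74 in the same order (adjusted p = 4.30e-10). In Brown Norway the respiratory chain assembly gene Bcs1l gave 1.42, the matrix gene Dpt 2.07 and Baalc -1.17, against 0.05, -0.39 and 0.58 in Fisher (adjusted p = 3.88e-08, 2.83e-08 and 7.41e-09).
At PN7 the count was 3508, or 1784 when only the groups compared were fitted. The B cell chemokine Cxcl13 gave -2.33 in Lewis, 0.08 in Fisher and 0.39 in Brown Norway (adjusted p = 5.00e-13), and the phosphodiesterase Pde2a gave 2.69, 0.21 and -0.12 (adjusted p = 6.03e-11). In Lewis the nucleotide hydrolase Dctpp1 gave -2.76, the pyrophosphatase Ppa1 -1.86 and the collagen gene Col14a1 -1.42, against 0.56, 0.41 and 0.48 in Brown Norway (adjusted p = 6.03e-11, 7.01e-11 and 6.03e-11). At PN14 limma called 0 probes for a difference between strains (184 at an unadjusted p under 0.05).

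Whether the exposure effect changed with age was tested within each strain. In Lewis 3595 probes were called, or 5478 with slide as a fixed term. The exposure difference of Ube2c was 0.73 at PN1, -2.98 at PN7 and -0.45 at PN14 (adjusted p = 1.20e-11), and that of the basement membrane collagen Col15a1 was 0.45, -3.46 and 0.15 (adjusted p = 2.88e-11). Cxcl13, Dctpp1 and Pde2a gave -2.33, -2.76 and 2.69 at PN7, against -0.05, -0.43 and 0.16 at PN14 (adjusted p = 1.20e-11, 1.42e-11 and 1.20e-11).
In Brown Norway 2395 probes were called. Gal gave -3.42, -0.08 and 0.21 at the 3 ages (adjusted p = 6.84e-08), and lipoprotein lipase (Lpl) gave -1.42, 0.36 and 0.10 (adjusted p = 1.92e-08). Bcs1l, Pon3 and the chaperone Pdia4 gave 1.42, 1.74 and 1.25 at PN1, against -0.11, -0.08 and -0.09 at PN14 (adjusted p = 2.81e-08, 3.01e-08 and 6.84e-08).
In Fisher 131 probes were called. Cpa4 gave 2.36 at PN1 and was at least 2.05-fold lower at PN7, where 1 of 3 saline arrays measured it (adjusted p = 0.000403), Ube2c gave -2.03, -0.21 and -0.25 at the 3 ages (adjusted p = 0.00126) and Srpx -0.56, 0.82 and -0.09 (adjusted p = 1.91e-06). Mup4 and Mup4l4 were at least 2.81-fold and 2.79-fold higher at PN1 (adjusted p = 0.000847 and 0.000847). The Fisher count was 71 with slide as a random block and 0 when only the groups compared were fitted (limma, 1222 probes at an unadjusted p under 0.05). It was 70 without PN1 saline replicate a, 69 without PN1 ovalbumin replicate b, 31 without PN7 saline replicate c and 61 without PN7 ovalbumin replicate d.

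A developmental index placed each array between the PN1 (0) and PN14 (1) saline arrays of the other two strains, over the probes that changed between these ages there (4077 probes for Lewis, 4333 for Fisher and 2604 for Brown Norway). Brown Norway PN1 ovalbumin arrays had a mean of 0.213 ± 0.0682 against -0.0470 ± 0.0483 for saline (SD, n = 4 each). The difference was 0.260 (exact two-sided permutation p = 0.0286, adjusted p = 0.129 over 9 tests). Lewis PN7 gave 0.123 ± 0.112 against 0.558 ± 0.119 (SD, n = 4 each, difference -0.435, exact permutation p = 0.0286, adjusted p = 0.129). Fisher PN1 gave 0.248 against 0.418 (difference -0.170, exact permutation p = 0.0571). The others were 0.0687 in Lewis PN1, -0.00820 in Fisher PN7 and -0.0251 in Brown Norway PN7. Lewis, Fisher and Brown Norway PN14 gave 0.0402, 0.0287 and -0.0220. None passed after adjustment, but 0.0286 is the lowest p this test can give. With the slide term removed 7 of 9 passed (exact permutation, adjusted p = 0.0367). Those in Brown Norway PN7 and at PN14 cannot tell slide from exposure. Fisher PN7 (0.0878, not past the test), Brown Norway PN7, Lewis PN14 and Fisher PN14 turned sign.

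**Figure D4:**
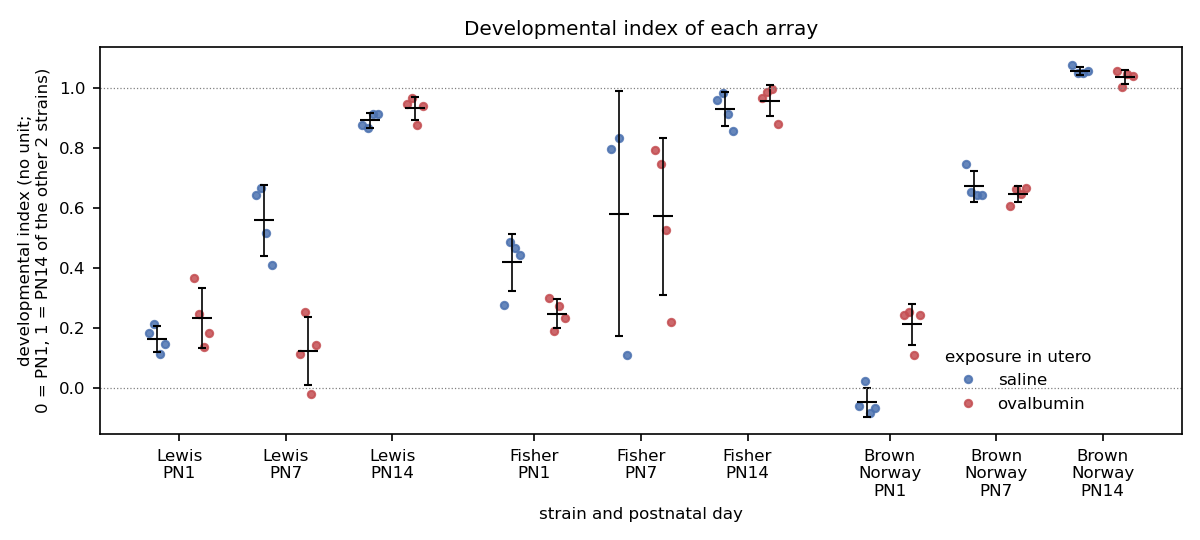
Developmental index (vertical axis, no unit) of each array by strain and postnatal day (horizontal axis), with points for single arrays and bars for the mean and SD of each exposure. Lewis PN7 ovalbumin arrays reach at most 0.255 and saline arrays at least 0.408.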

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

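Tests below of slide, younger animals, varying state, Fisher PN7 saline c and Lewis PN1 ovalbumin a were chosen only after the result was seen. A gene named in the report was listed where 1 array of a group of 4 lay further from the others than the 95% critical value of Dixon's test allows, and where a test of the difference itself showed that 2 groups responded differently.

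An array lay far from the other 3 in 82 of 978 groups of values (8.38%), against about 1 in 20 by chance. Log2 signals are in parentheses. In Lewis PN1 saline, replicate a was low for Plk1 (6.92) and RT1-S2 (4.46). Replicate b was high for Ube2c (9.04). Replicate c was high for Mup5 (10.60), Sorbs2 (9.68) and Stfa3 (10.11) and low for Spon2 (8.01). In Lewis PN1 ovalbumin, replicate a was high for Ccl19 (10.24), Cd3g (13.20), Cd8a (12.64), Mmp12 (7.46) and Ptprcap (12.75). In Lewis PN7 saline, replicate b was high for Thrsp (5.87) and Ucp1 (10.41) and low for Mfap4 (13.91). Replicate c was high for Odc1 (9.76). Replicate d was high for Afp (11.38), Ahsg (11.98), Alb (12.16) and Apoc1 (10.01) and low for Angptl2 (6.81), Nell1 (5.60) and Spon2 (8.89). In Lewis PN14 saline, replicate a was low for Sorbs2 (7.85). Replicate b was high for Ahsp (10.97), Gata1 (5.31) and Myh3 (7.02) and low for Slfn4 (8.12). Replicate c was low for Cav2 (11.24).

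In Fisher PN1 saline, replicate a was high for Fkbp5 (13.29), Klkb1 (8.39), Pcdh20 (8.76), Spp1 (8.25) and Zbtb16 (6.71) and low for Aqp5 (8.28) and Nell1 (6.21). Replicate b was high for Tek (9.34). Replicate d was high for Col3a1 (12.73) and Ucp1 (9.01). In Fisher PN1 ovalbumin, replicate b was high for Aqp5 (10.27), and replicate c was high for Ccl19 (9.48). In Fisher PN7 ovalbumin, replicate c was high for Il1b (9.07). In Fisher PN14 saline, replicate c was high for Postn (14.25) and low for Hopx (14.27), and replicate d was high for Alb (6.58) and Sorcs3 (6.11) and low for Mcm5 (6.05), Plk1 (7.09) and Ucp1 (8.28).

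In Brown Norway PN1 saline, replicate b was high for Ckm (9.86) and Mcm2 (9.16) and low for Mlc1 (8.03) and Tek (9.99). Replicate c was high for Bmal1 (8.54) and Lst1 (5.47) and low for Cd8a (5.65). Replicate d was high for Dynlrb2 (10.07). In Brown Norway PN1 ovalbumin, replicate b was high for Gbp2 (10.34), and replicate c was low for Slc7a10 (8.57) and the developmental index (0.111). In Brown Norway PN7 saline, replicate a was high for Klkb1 (5.76), Plekhh1 (6.11) and the developmental index (0.746). Replicate b was high for Dpf2 (8.13), RT1-CE16 (12.29) and Spon2 (11.78) and low for Cdc20 (9.82), Hopx (13.95), Kit (8.01), Lox (11.69), Rpl30 (13.25), Synpo2 (6.79) and Washc3 (10.76). Replicate c was high for Tek (9.62) and low for Mfap4 (13.87). Replicate d was high for Myh3 (7.54) and low for Esm1 (5.10). In Brown Norway PN7 ovalbumin, replicate a was high for Cbs (6.09). In Brown Norway PN14 saline, replicate a was high for Ifi47 (4.88). Replicate c was high for Lcn2 (10.07). Replicate d was high for Nell2 (5.02) and low for Defa5 (5.20).

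The exposure effect or age profile differed between groups by its own F test for 5190 probes (age profile by strain), 3175 and 3508 (exposure by strain at PN1 and PN7), and 3595, 131 and 2395 (exposure by age in Lewis, Fisher and Brown Norway). Among the named genes, given with the largest minus the smallest log2 effect, the age profile differed between strains for Pon3 (2.95), Mup4l4 (4.25), Mup4l3 (3.41), Fcer1a (2.38) and Obp3 (2.95). The exposure effect differed between strains for Bcs1l (1.41), Pon3 (2.22), Prg4 (3.33), Baalc (1.75) and Dpt (2.45) at PN1, and for Cxcl13 (2.71), Dctpp1 (3.33), Ppa1 (2.27), Pde2a (2.81) and Col14a1 (1.90) at PN7. Between ages it differed for Cxcl13 (2.28), Dctpp1 (3.34), Ube2c (3.72), Col15a1 (3.90) and Pde2a (2.95) in Lewis, for Mup4l4 (2.27), Cpa4 (3.84), Ube2c (1.82), Mup4 (2.63) and Srpx (1.38) in Fisher, and for Bcs1l (1.53), Pon3 (1.82), Lpl (1.77), Pdia4 (1.36) and Gal (3.63) in Brown Norway. For Fcer1a, Obp3, Mup4l3, Mup4l4, Mup4 and Cpa4 some groups were below background, so these values are not exact.

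Arrays were also regrouped into splits of the same sizes, the real one included. With 100 drawn splits chance was argued against where under 5 of 100 gave as many probes, without adjustment over the comparisons. Only the real one did for the steps from PN1 to PN7 (6585, highest other 2859) and PN7 to PN14 (6314 and 4183), the age profile by strain (5190 and 1968), Brown Norway against Lewis (3275 and 1698), Fisher against Lewis (2193 and 1830) and Brown Norway against Fisher (4519 and 2067). The same held for the means of strains at PN1 (1529 and 1201) and PN7 (3175 and 2421), exposure by strain at PN1 (3175 and 2705), and exposure by age in Lewis (3595 and 3262) and Brown Norway (2395 and 1975). For exposure by strain at PN7 4 did (3508, highest other 4941), close to that limit, with larger counts in others. For the mean of strains at PN14 2 did (2 and 3), counts too low to tell. Chance cannot be excluded for exposure by age in Fisher (10 of 100, 131 and 1304) or exposure by strain at PN14 (100 of 100, 0 by limma with 184 at an unadjusted p under 0.05, and 4). The 1304 probes, several times the real count, point to a structure of the Fisher arrays. As splits break up the whole exposure effect, they do not test whether it differed by strain or age. Within 1 strain and age there are 35 splits, and 1 gave as many in Lewis PN1 (24 and 5), Fisher PN1 (386 and 45), Brown Norway PN1 (3684 and 1626), Lewis PN7 (4938 and 2332) and Brown Norway PN7 (21 and 2), so chance can be excluded. In Brown Norway PN14 1 gave as many too (1 and 0, limma, 380 at an unadjusted p under 0.05), counts too low to tell. Other splits gave as many in Fisher PN7 (7 of 35, 281 and 2182), Lewis PN14 (35 of 35, 0 by limma with 348 at an unadjusted p under 0.05, and 1) and Fisher PN14 (2 of 35, 2 and 4), so chance cannot be excluded there. In Fisher PN7 the 2182 came from ovalbumin c and d with saline c against the rest. That split parts no pair of letters, follows slide 4 against the other slides and points to a structure of the samples. Of the 8 splits that part all 3 pairs, too few for a share under 0.05, the real one gave 281 and the highest other 1. In Brown Norway PN7 and at PN14 the real split itself follows the slides.

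Differences between exposures in Lewis PN7 and Brown Norway PN1 were large and opposite. Slide alone is argued against: over the 2880 probes called within slide 2 in Lewis PN7, the median change within slide 4 was 0.574 of that in slide 2 with 92.2% in the same direction, and over the 983 Brown Norway PN1 probes called and changed over 2-fold between slide 1 saline and slide 2 ovalbumin arrays, the change within slide 3 was 0.733 of that, with 98.4% in the same direction. The latter replaced a test (0.899) on probes chosen over all arrays, void because slide 3 enters the choice. Younger ovalbumin animals in Lewis PN7 stay open. Their median position between PN1 (0) and PN7 (1) saline was 0.449 (quartiles -0.0621 to 0.735, 151 probes). Their developmental index was 0.123, against 0.164 in Lewis PN1 and 0.558 in Lewis PN7 saline. A candidate explanation is a state that also varies between animals of 1 exposure: the Lewis PN7 change carried 4.12% of the variation within the 14 groups in neither comparison, against 0.651% along a strain difference, and the Brown Norway PN1 change 3.97% against 0.641%. Much of this lies on the Fisher PN7 arrays, as without them the shares were 1.64% against 0.647% and 1.47% against 0.560%, too close to tell. That test replaced a first one against the leading component of this variation, where the cosines were 0.0288 and 0.0125 (0.454 and 0.456 with component 2), so it is a hypothesis. Litter differences (litters are not recorded) and an effect of ovalbumin both stay open, untested.

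Fisher PN7 saline replicate c lay apart from replicates a and b. A dim array is argued against: its median raw signal was 149 (other Fisher PN7 arrays 135 to 145). Probes detected were 10497 (10164 on ovalbumin d, 10797 to 11209 on the others). A wrong age label stays open. The median position of replicate c between Fisher PN1 saline (0) and replicates a and b (1) was 0.464 over 150 probes. The ovalbumin arrays had 0.749 to 1.07. On the developmental index replicate c had 0.109 and ovalbumin d 0.220, below all Fisher PN1 saline arrays (0.277 to 0.488).

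T cell genes were high in Lewis PN1 ovalbumin replicate a, with a median 5.62 above replicates b to d over 9 genes. Thymus tissue in the sample is a candidate source: the median of 4 thymocyte genes was 3.46 above the other replicates. Lymphocytes in general may contribute, the median of 4 B cell genes being 0.620 above, which leaves them open. A response to ovalbumin in 1 animal was not tested.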

How the results depend on the processing

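Leaving out the 4 arrays in doubt and the block by pair in Fisher PN7 were chosen only after the result was seen, and the other alternatives were fixed before. A count is given where it moved by over 1.5 times, and the cause was not tested for any of them.

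With the authors' deposited values, as without background correction, Lewis PN1 gave 13 probes (6 higher and 7 lower) and Fisher PN14 0 by limma, with 589 and 588 at an unadjusted p under 0.05. Without the detection filter the counts were 172 in Fisher PN7, 1 in Brown Norway PN7, 1 in the mean at PN14 and 82 for exposure by age in Fisher. With slide as a fixed term they were 3662 (PN7 against PN1), 3502 (PN14 against PN7), 710 (Fisher PN1), 6 (Fisher PN7), 793 (Brown Norway PN7), 790, 1955 and 1572 (means at PN1, PN7 and PN14), 5478 (exposure by age in Lewis), and 1486, 692 and 694 in Lewis, Fisher and Brown Norway PN14, which rest on Fisher PN14 ovalbumin d. With slide as a random block (correlation 0.0721) they were 71 for exposure by age in Fisher, 1 in Fisher PN14 and, by limma, 0 in Brown Norway PN7 (2008 at an unadjusted p under 0.05), Brown Norway PN14 (225) and the mean at PN14 (379). With only the groups compared they were 236 (Fisher PN1), 52 (Brown Norway PN14), 1772 and 13 (means at PN7 and PN14), 1784 (exposure by strain at PN7) and, by limma, 0 for Lewis PN1 (1793 at an unadjusted p under 0.05), Fisher PN7 (1356), Brown Norway PN7 (1018), Fisher PN14 (543) and exposure by age in Fisher (1222). Without the 4 arrays in doubt they were 8 in Lewis PN1, 184 in Fisher PN7, 4 in the mean at PN14 and 45 for exposure by age in Fisher.

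Fits within 1 slide use fewer arrays. Fisher against Lewis gave 550, 504, 848 and 378 on slides 2 to 5, Brown Norway against Lewis 739, 469 and 651 and Brown Norway against Fisher 1270, 1686 and 1053 on slides 3 to 5. Lewis PN7 gave 2880 on slide 2 and 1926 on slide 4, Brown Norway PN1 700 and the mean at PN1 35 on slide 3, and limma 0 for Lewis PN1 on slide 3 (853 at an unadjusted p under 0.05) and Fisher PN7 on slide 4 (587). Of the gene lists, 103 were called with the preset correlation and 3 with an estimated one, and 37 of the 103 lost their call in some fit without 1 array, tests added after the result was seen.

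With replicate letter as a block over all arrays no count moved by over 1.5 times (3705 in Brown Norway PN1 and 4949 in Lewis PN7). Of 35 pairs of arrays with the same letter 12 had a correlation of deviations over 0.1 (median 0.00390, range -0.355 to 0.433), and only Fisher PN7 had no pair under it. With the replicate block by pair there the count was 22, and 17 of 19 called gene results and 6 of 8 gene lists lost their call.

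Leaving out 1 array gave 6085 to 6717 probes for PN7 against PN1, 5783 to 6460 for PN14 against PN7, 4289 to 5839 for the age profile by strain, 2976 to 3385 (Brown Norway against Lewis), 1866 to 3006 (Fisher against Lewis) and 4135 to 4744 (Brown Norway against Fisher). The ranges were 2814 to 3832 in Brown Norway PN1, 4066 to 4997 in Lewis PN7, 1113 to 2065 and 2516 to 3361 for the means at PN1 and PN7, 2502 to 3456 and 2888 to 3781 for exposure by strain at PN1 and PN7, and 2788 to 3697 and 1751 to 2987 for exposure by age in Lewis and Brown Norway. Lewis PN1 ran from 6 to 131, Fisher PN1 from 169 to 354 and Fisher PN7 from 8 (ovalbumin d) to 541. Brown Norway PN7 ran from 0 by limma (1066 at an unadjusted p under 0.05 without saline b) to 599, and exposure by age in Fisher from 31 to 195. At PN14 the ranges were 0 to 0 (Lewis), 0 to 2 (Fisher), 0 to 1 (Brown Norway), 1 to 4 (mean) and 0 to 1 (exposure by strain), against limma counts at an unadjusted p under 0.05 of 348, 588, 380, 1045 and 184 over all arrays.

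For the developmental index, removing the slide term brought 7 differences to adjusted p = 0.0367 (exact permutation): 0.118 (Lewis PN1), 0.347 (Brown Norway PN1), -0.529 (Lewis PN7) and -0.298 (Brown Norway PN14), and, with the sign turned, 0.235 (Brown Norway PN7), -0.145 (Lewis PN14) and -0.270 (Fisher PN14). In the PN14 and Brown Norway PN7 tests slide and exposure cannot be told apart. Over fits without 1 array it ran from 0.0239 to 0.101 (Lewis PN1), -0.217 to -0.147 (Fisher PN1), 0.246 to 0.294 (Brown Norway PN1), -0.485 to -0.387 (Lewis PN7), -0.243 to 0.118 (Fisher PN7), -0.0347 to -1.49e-04 (Brown Norway PN7), 0.0286 to 0.0587 (Lewis PN14), 0.00479 to 0.0545 (Fisher PN14) and -0.0287 to -0.0106 (Brown Norway PN14), and none passed. Of 604 named gene results, slide as a fixed term reversed 1 (Lcn2 between PN1 and PN7, 0.0325), weakened 80 and strengthened 6.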

Other observations

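The liver list and the overlaps were examined only after the result was seen. Over 13 liver genes, Fisher PN1 saline replicate a (5.08), Lewis PN7 saline replicate d (4.23), Fisher PN14 ovalbumin replicate c (2.31) and Lewis PN7 ovalbumin replicate b (2.20) lay above the other arrays of their groups. Fisher PN1 shared 272 called probes with Lewis PN7 (136 by independence), 242 in the same direction, with Pearson's r = 0.360 across probes. The adipose and airway secretory lists were called in no comparison, and no sex-linked gene of the fixed list was measured.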
